A study of Mus musculus with 6 samples.

How the data were processed

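Total RNA from the lungs of 3 control and 3 mutant mice was amplified from 550 ng per sample into biotin-labelled cRNA and hybridised to Illumina mouse bead arrays, per the labels' protocols. The groups were taken from the sample titles and genotypes. The mice are separate animals, so the p-values of probes set differences against the spread between mice. Per the file headers, the deposited unnormalized table gives for each array and probe an intensity, on a linear scale, and a detection p-value. GenomeStudio 2009.2 and R 2.4.1 are named in the submitters' processing notes without a role. The chip each array sat on, the scan and any background subtraction are not given in the sources used here. A second table holds the authors' processed values for 13261 probes, which follow the log2 of the intensity within each deposited column and are quantile normalized, with a median of 9.57 in each column. They are not centred, and their filter is not stated. In that deposited log2 table, the column of mutant mouse 1 is identical to that of mutant mouse 2 at all 13261 probes and follows the intensities of mutant mouse 2 (rank correlation 1, against 0.990 with the array of mutant mouse 1). Other pairs of columns share 2 to 24 values, and no unnormalized array shares a value of any probe with another. The unnormalized table was therefore used for every result, and the processed table, with 3 controls and 2 distinct mutants, as an alternative.

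Intensities were background corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which fits a normal-exponential model to negative controls, here inferred from the detection p-values (about 798 control beads are implied), adds an offset of 16, applies quantile normalization and takes log2. Probes with a detection p below 0.05 on at least 3 of the 6 arrays, whatever their group, were tested, which left 13361 of 25697. Of the 12495 probes that the platform annotation pairs with a single gene symbol, 12490 had their symbol updated by Entrez gene identifier through the RefSeq genes of assembly GRCm38.p6 and 5 kept the older one. No probe had several symbols. The array's own genome build is not given in the sources used here, so no coordinates are printed. Among tested probes, 12429 had a symbol and 932 were unnamed here, and 766 probes of the processed table were unnamed. A gene was represented by its tested probe with the highest mean over all 6 arrays. Where a probe was detected on no array of a group, a fold is given as a bound: the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value among detected probes. Where it was detected on some arrays of a group, their number is given. Arrays have no read depth, and a probe near the background gives an understated fold.

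Mutants were compared with controls by lmFit and eBayes of limma, without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all tested probes. Errors beside log2 differences are standard errors of the fit with 3 mice per group. Before the data were examined, 38 gene lists were fixed for lung cell types, vessels, signalling pathways and stress responses. The 35 with at least 5 measured genes were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists. Camera sets the genes of a list against other genes, so its p-values at that setting do not measure the spread between mice. Fisher's exact test and exact limits, where given, count genes as independent units. The list calls were repeated with an estimated correlation, where 0 of 35 lists passed and the lowest adjusted p was 0.344, and with fry, a rotation test that does not compare a list with other genes. Genes named in the text followed a rule fixed at the same time: Tmem100; the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, leaving out clone, locus and RIKEN names; and up to 4 members of each described list, those past the threshold with the largest change, else the 2 with the lowest p. Named beside these after their values were seen are Flt1, Adgrl4, Pecam1, Id1, Egr1, Myl4, Phlda3, Ccng1, Hba-a1, Nppa and the genes of the added list.

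The fitting and list tests were first tested on data simulated from the means and spreads of the 13361 probes. With 200 changed probes, 77% of 2-fold and 98% of 4-fold changes were recovered, and 12 of 187 calls were false. With no change, 0 probes and 0 lists were called. Each setting was drawn a single time, with noise independent between probes. The simulation therefore cannot show how often lists of genes that vary together would be called falsely. Its changed probes were also a far smaller share than passed in the data. Alternatives were normexp with an offset of 50, no background correction, median scaling, the deposited processed values, no filter and a detection p below 0.01 on all 6 arrays, a variance trend with robust settings, array weights, the mouse number as a block, leaving out each mouse, adjusted p below 0.10, a 1.5-fold minimum, and for lists an estimated correlation, the mean of all probes of a gene and fry. A list of glucocorticoid-induced genes and a difference of medians for Tmem100 were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.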

Results

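RNA from whole adult lungs of 6 mice was profiled on Illumina bead arrays, a single array per mouse. TMEM100 is a small transmembrane protein of endothelial cells whose gene is induced by signalling through the receptor ALK1. All 6 mice were homozygous for a Tmem100 allele flanked by loxP sites, and all received 2 tamoxifen injections of 0.1 mg per g of body weight. The 3 mutant mice also carried CreER, a Cre recombinase that tamoxifen activates, knocked into the ROSA26 locus, while the 3 control mice carried no CreER. Lungs were taken 7 days after tamoxifen. The comparison addresses which lung transcripts differ after treatment meant to delete Tmem100 in the adult. Recombination of the allele was not measured here. Each array reported 25697 probes, with a median intensity between 333 and 363. Between 13354 and 13749 probes were detected on the control arrays and between 12781 and 13046 on the mutant arrays. The number of arrays limits the precision of every value.

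Tmem100 was measured by a single probe, which was detected on all 6 arrays. Its normalized log2 intensity was 11.16, 15.36 and 10.69 in control mice 1, 2 and 3, and 8.44, 9.43 and 9.51 in mutant mice 1, 2 and 3. All 3 mutants lay below all 3 controls, and the mutant mean was 9.68-fold lower, a log2 difference of -3.28 ± 1.15 (SE). The difference did not pass the threshold in limma's moderated test (adjusted p = 0.0749), and the SD was 2.57 among controls and 0.60 among mutants. Control mouse 2 decided this outcome: without it, the log2 difference was -1.80, a 3.49-fold lower level, and the adjusted p was 0.0284. The position of the probe relative to the deleted part of the gene is not given in the sources used here, so whether the probe reports the deletion is not known.

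**Figure D1:**
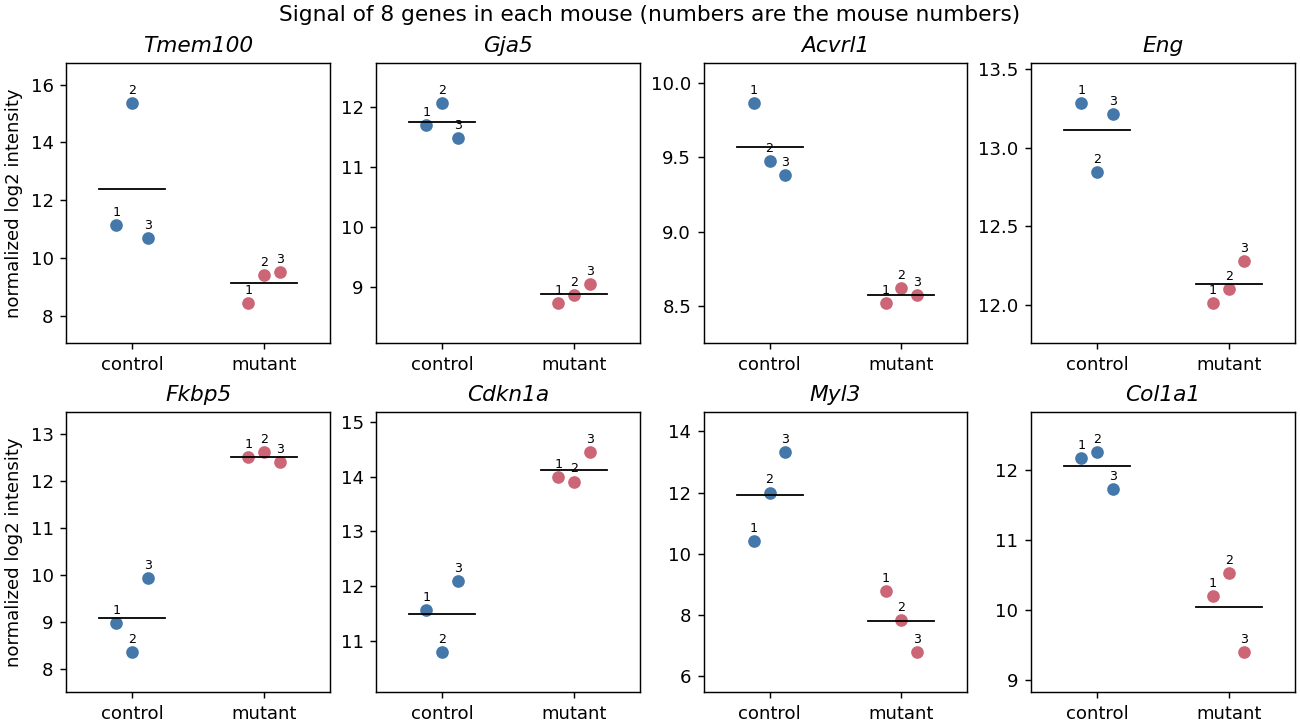
Normalized log2 intensity (vertical axes, which differ in range) of 8 genes in each control mouse (blue) and mutant mouse (red), with the mouse number above each point and the group mean as a line. Tmem100 lay at 15.36 in control mouse 2 and at or below 11.16 in the other mice, while the values of Gja5 lay near 11.76 in controls and near 8.88 in mutants.

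Mutant lungs differed from control lungs over a large part of the transcriptome. Of 13361 probes tested, 3573 (26.7%) passed an adjusted p of 0.05, 1774 of them higher and 1799 lower in mutants. With a single probe for each gene, 2552 of 9383 genes passed, 1195 higher and 1357 lower. Of these, 297 genes were at least 2-fold higher and 454 at least 2-fold lower. The groups did not overlap for 6348 probes (47.5%), where random splits give 10% on average. Probes vary together, so this share does not exclude chance or a factor shared by the mice of a group. The correlation of log2 values across probes, which are not independent replicates, was 0.979 to 0.987 between controls, 0.979 to 0.991 between mutants and 0.931 to 0.972 across groups. The count of probes past the threshold was 1679 without control mouse 1, 2104 without control mouse 2 and 2060 without mutant mouse 1. For 15 genes, different probes passed in opposite directions.

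The genes with the largest rises included regulators of growth and of steroid receptors. Doc2b, a calcium sensor of vesicle release, rose most, by 6.06 ± 0.25 on the log2 scale (SE; adjusted p = 2.77e-04). Its probe was detected on 1 of the 3 control arrays, and a second Doc2b probe also rose. Fkbp5, a co-chaperone of steroid hormone receptors, was 10.8-fold higher (log2 3.44 ± 0.36, adjusted p = 0.00305). Ddit4, an inhibitor of the growth kinase complex mTORC1, was 7.53-fold higher (log2 2.91 ± 0.16). Cdkn1a, which encodes the cell cycle inhibitor p21, was 6.21-fold higher (log2 2.63 ± 0.33), and all 3 of its probes rose. Pmvk, an enzyme of isoprenoid synthesis, was 10.6-fold higher, with mutant values of 11.18 to 13.23. Gldc, of the glycine cleavage system, was 9.45-fold higher and the transcription factor Tcf23 9.33-fold higher, each with a probe detected on 1 of the 3 control arrays. Kcnip3, a calcium-binding protein, rose 8.52-fold, Myrip, which links Rab27 to myosin, 8.48-fold, and Fam107a, an actin-associated protein, 7.90-fold. Pcdh20, a protocadherin, rose 6.19-fold. A probe for Ear6, detected on 2 of the 3 control arrays, was 6.16-fold higher, but Ear6 belongs to a family of near-identical ribonuclease genes, so which of them it measured is uncertain. The adjusted p of these 12 genes ranged from 2.77e-04 to 0.012. The folds of probes that are dim in controls depended on background correction, and without it 8 of the 12 were over 1.5 times smaller: Doc2b rose 11.3-fold, Pmvk 6.37-fold, Fam107a 4.04-fold, Kcnip3 2.84-fold, Gldc 2.77-fold, Tcf23 2.65-fold, Ear6 2.43-fold and Pcdh20 2.13-fold.

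The largest falls included genes of striated muscle and of elastic fibres. Car3, a carbonic anhydrase abundant in muscle and fat, was not detected on any mutant array and was at least 11.5-fold lower (adjusted p = 0.0081). Its log2 intensity was 8.52, 11.62 and 8.71 in control mice 1, 2 and 3, so this bound on the group means leans on control mouse 2. Myl3, a myosin light chain of heart and slow muscle, was 17.3-fold lower (log2 -4.11 ± 0.78), and Actc1, cardiac actin, was 9.56-fold lower (log2 -3.26 ± 0.52). Adipoq, the fat cell hormone adiponectin, was 10.7-fold lower but was detected on 1 mutant array. The muscle creatine kinase gene Ckm was at least 5.37-fold lower, and Scn3b, a sodium channel subunit, at least 3.94-fold lower, with neither detected in mutants. The amino acid transporter genes Slc38a5 and Slc7a10 were 9.67-fold and 8.49-fold lower. Myl1, a myosin light chain of fast muscle, was 8.10-fold lower. Gja5, which encodes connexin 40 of arterial endothelium, was 7.32-fold lower (log2 -2.87 ± 0.18, adjusted p = 0.00165), with both of its probes falling. The elastic fibre genes Mfap4 and Fbln1 were 6.99-fold and 6.67-fold lower. The calls of Adipoq, Ckm and Myl1 were lost when some mice were left out: for Adipoq without control mouse 1 or any of the 3 mutants (adjusted p up to 0.101), and for Ckm (up to 0.0897) and Myl1 (up to 0.0736) without control mouse 2 or any of the 3 mutants. Without control mouse 2 the log2 difference of Adipoq was -2.28, and without control mouse 3 that of Ckm was -1.98. Calls also ended with the deposited processed values for Car3 (adjusted p = 0.0905), Adipoq (0.171), Ckm (0.173) and Myl1 (0.0613), without background correction for Adipoq (0.0860) and Ckm (0.0939), without the filter for Adipoq (0.0629) and Ckm (0.0577), with a variance trend for Adipoq (0.0756), Ckm (0.0521) and Myl1 (0.0531), and with array weights for Ckm (0.0649) and Myl1 (0.0618). The bounds and folds are those of background-corrected values: without that correction 6 of the 12 were over 1.5 times smaller, Myl3 being 8.14-fold, Car3 4.22-fold, Adipoq 3.44-fold, Slc7a10 2.99-fold, and Scn3b and Ckm each 2.41-fold lower.

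The arterial, pan-endothelial and general capillary marker lists shifted down in mutants. Of 14 arterial endothelial markers measured, 10 fell and none rose (11 fell adjusted over the list alone), with a median log2 change of -0.90. Besides Gja5, the chemokine gene Cxcl12 was 3.69-fold lower (log2 -1.88 ± 0.16), the matrix gene Fbln2 2.69-fold lower and the VEGF co-receptor gene Nrp1 2.17-fold lower. The list shifted down in camera's test with a preset correlation (adjusted p = 1.25e-04), but its adjusted p = 0.344 with an estimated correlation. Without control mouse 1, 6 of the markers passed. Of 22 pan-endothelial markers, 10 fell and 2 rose (12 and 2 adjusted over the list alone), and the list shifted down (adjusted p = 0.00584; adjusted p = 0.624 with an estimated correlation). Emcn and Cd93 were each lower by 1.16 on the log2 scale, Sox17 was lower by 0.97 and Icam2 by 0.95, whereas the VEGF receptor gene Flt1 and Adgrl4 rose by 0.69 and 0.63. Pecam1 differed by -0.03 ± 0.12 and did not pass. Without control mouse 1, 5 pan-endothelial markers fell, and the call of Sox17 was lost (adjusted p = 0.0515). Of 9 general capillary markers, 5 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.90, and the list shifted down (adjusted p = 0.0144; adjusted p = 0.444 with an estimated correlation). Its riser was the lipoprotein lipase gene Lpl, 2.02-fold higher. Of 8 aerocyte capillary markers 4 fell, led by Car4 (2.43-fold), and none rose (4 fell and 1 rose adjusted over the list alone), but the list did not pass (adjusted p = 0.0662). It did pass without mutant mouse 3 (adjusted p = 0.0277), with array weights (0.0409), with the mean of all probes of a gene (0.0406) and in fry (0.00937), and 1 member rose without control mouse 3.

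Genes of the BMP9 and ALK1 signalling pathway did not move in 1 direction. Of 22 measured, 3 rose and 5 fell (5 and 5 adjusted over the list alone), with a median of 0.07, a mean of -0.01 and no shift in camera's test (adjusted p = 0.947). The receptor gene Acvrl1, which encodes ALK1, was 2.00-fold lower (SE 0.15 on the log2 scale, adjusted p = 0.00617), and the co-receptor gene Eng was 1.98-fold lower (log2 -0.98 ± 0.15, adjusted p = 0.00679). Whether these falls are separate from the fall of the pan-endothelial markers was not tested. The co-receptor gene Tgfbr3 was 2.50-fold higher (log2 1.32 ± 0.20) and the transcription factor gene Hey2 2.15-fold higher (log2 1.10 ± 0.14). The direct ALK1 target Id1 differed by 0.36 and did not pass. With any 1 mouse left out, 2 members rose. Those that fell were 2 without control mouse 1, 3 without mutant mouse 1 and 4 without any 1 of the other mice. Of 13 Notch pathway genes, 1 rose and 3 fell (1 and 4 adjusted over the list alone), with no shift of the list (adjusted p = 0.713). Hey2 was the riser (1.36-fold without background correction), while Hey1 (log2 -0.86 ± 0.19), the feedback inhibitor Nrarp (-0.80 ± 0.15) and the ligand gene Dll4 (-0.65 ± 0.12) were lower. The call of Hey1 was lost without control mouse 1 or 2 (adjusted p up to 0.0684) and that of Dll4 without control mouse 1 (0.05005). Of the Notch list, 1 member fell without control mouse 1. Hey1 and Hey2 are also in the BMP9-ALK1 list, and Hey1 and Dll4 in the arterial list.

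**Figure D2:**
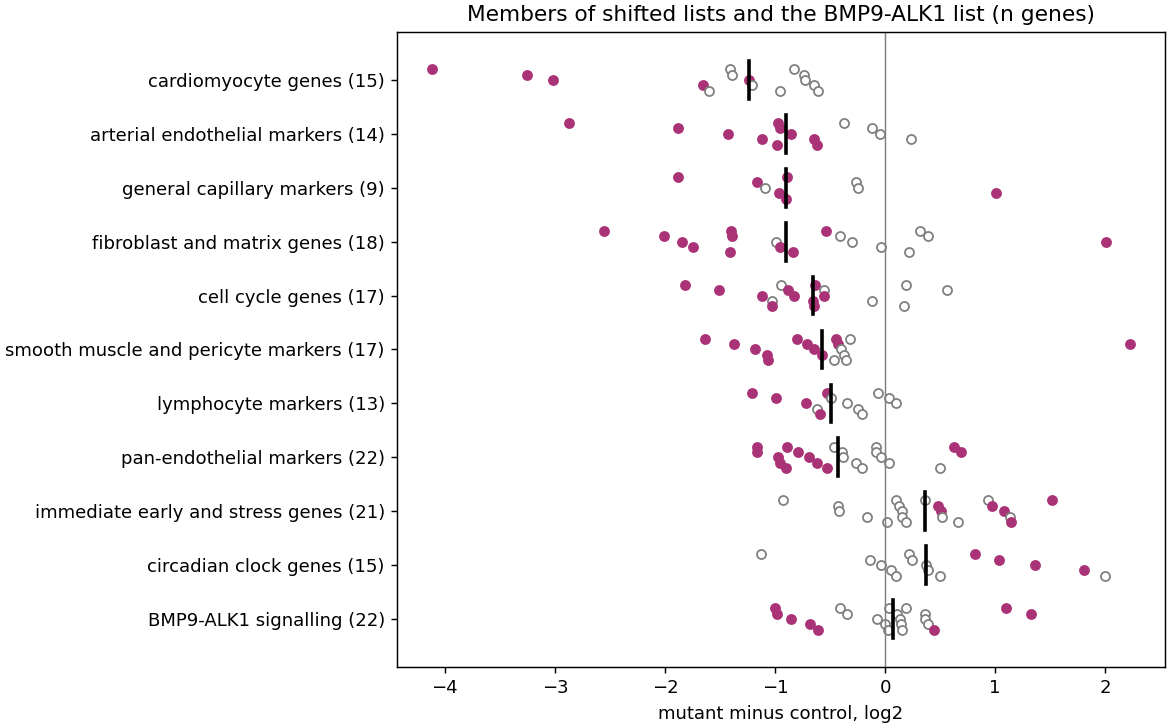
Difference between mutant and control means (horizontal axis, log2) of each measured member of the 10 lists that shifted in camera's test and of the BMP9-ALK1 list. Filled points passed an adjusted p of 0.05, open points did not, and black bars are list medians. The medians run from -1.23 for cardiomyocyte genes to 0.37 for circadian clock genes. The point of Rgs5, the riser at 2.22 in the smooth muscle list, was below detection on every control array.

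The smooth muscle and the fibroblast and matrix lists shifted down as well. Of 17 smooth muscle and pericyte markers, 11 fell and 1 rose (11 and 1 adjusted over the list alone), and the list shifted down (adjusted p = 4.29e-04; adjusted p = 0.444 with an estimated correlation). The smooth muscle actin genes Actg2 and Acta2 fell by 1.63 ± 0.21 and 1.37 ± 0.20 on the log2 scale, with all 4 Acta2 probes falling, and tropomyosin 2 (Tpm2) by 1.19 ± 0.23. The pericyte marker Rgs5 went the other way, at least 3.45-fold higher, undetected on the control arrays, but 1.60-fold higher without background correction. Of the smooth muscle list, 5 members fell without control mouse 1, 6 without control mouse 2 and 6 without mutant mouse 1. Of 18 fibroblast and matrix genes, 10 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.90 and a downward shift (adjusted p = 0.00469; adjusted p = 0.444 with an estimated correlation). The collagen genes Col3a1 and Col1a1 fell by 2.55 ± 0.41 and 2.01 ± 0.30, Col3a1 being detected on 1 mutant array and 1.98-fold lower without background correction. The collagen cross-linking enzyme gene Lox was the exception, 4.02-fold higher (log2 2.01 ± 0.39). Of the matrix list, 2 members rose without mutant mouse 3.

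Cardiac muscle genes gave the largest median change of any shifted list. Of 15 measured, 5 fell (10 adjusted over the list alone), all 15 had a negative difference, and the list shifted down (adjusted p = 4.29e-04; adjusted p = 0.736 with an estimated correlation; fry adjusted p = 0.0944). The members that fell were Myl3, Actc1, Myl1, Ttn (3.16-fold) and Myl4, of which Ttn is common to all striated muscle and Myl1 is best known from fast skeletal muscle. The count was 3 without control mouse 2, mutant mouse 2 or mutant mouse 3, and the call of Myl4 was lost without any 1 of the 6 mice (adjusted p up to 0.121), without the filter (0.0745), with a variance trend (0.0599) and with array weights (0.0628). The control mice also differed from each other: the mean of the list was 10.6, 11.8 and 10.9 in control mice 1, 2 and 3, and 10.1, 9.43 and 9.10 in mutant mice 1, 2 and 3. Of 5 skeletal muscle genes, Ckm and Mb fell (2 adjusted over the list alone; list adjusted p = 0.0528). The skeletal list passed, shifted down, without control mouse 1 (adjusted p = 0.00459), control mouse 2 (0.0427), control mouse 3 (0.0338) or mutant mouse 1 (0.0410), with median scaling (0.0393), with a variance trend (0.0400) and with the mean of all probes of a gene (0.0467), and 3 of its members fell without control mouse 1 or 3 and 1 without any 1 of the other mice. The mean of the skeletal list was 11.8 in control mouse 3 against 8.45 and 9.15 in control mice 1 and 2, and 7.32 to 7.87 in mutants. Of 6 adipocyte genes 1 fell and 1 rose (1 and 1 adjusted over the list alone; list adjusted p = 0.947, with camera's direction up and a mean of -0.65), and the mean of the list was 9.99 in control mouse 2 and 8.04 to 8.33 in the other 5 mice. Of the adipocyte list 0 fell without control mouse 1 or any 1 mutant, and 2 rose without control mouse 2.

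**Figure D3:**
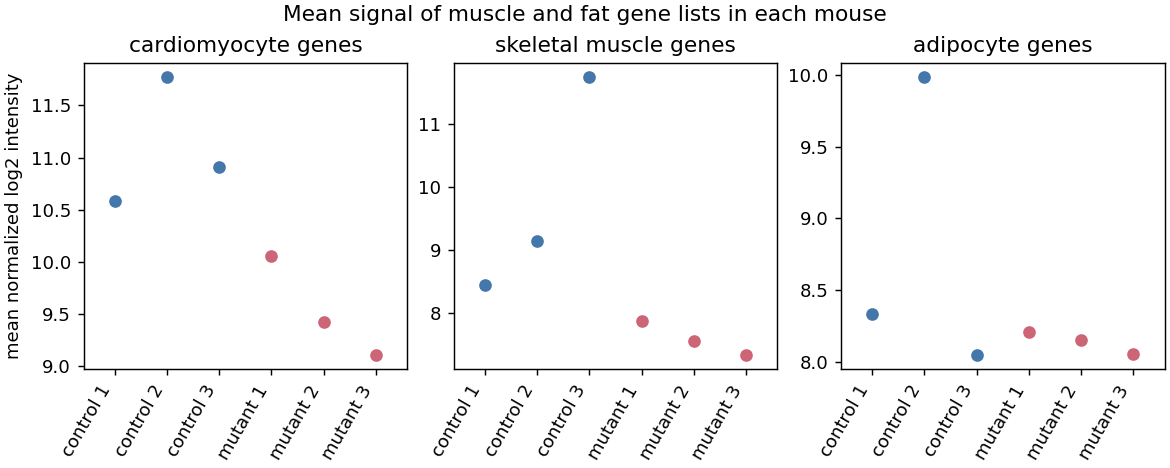
Mean normalized log2 intensity (vertical axes, which differ in range) of the cardiomyocyte, skeletal muscle and adipocyte lists in each control mouse (blue) and mutant mouse (red). Cardiomyocyte genes were at 9.10 to 10.1 in mutants and 10.6 to 11.8 in controls, skeletal muscle genes were highest in control mouse 3 (11.8), and adipocyte genes were highest in control mouse 2 (9.99).

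The cell cycle and lymphocyte lists shifted down in camera's test with the preset correlation, though 8 of the 13 lymphocyte markers did not pass. Of 17 cell cycle genes, 10 fell and none rose (11 fell adjusted over the list alone), and the list shifted down (adjusted p = 0.00584; adjusted p = 0.624 with an estimated correlation). Prc1, of the cytokinesis apparatus, fell by 1.82 ± 0.37, the thymidine kinase gene Tk1 by 1.51 ± 0.35 and the mitotic kinase gene Cdk1 by 1.12 ± 0.26, the last 2 detected on 2 mutant arrays. Without background correction these 3 were 2.20-fold, 1.42-fold and 1.25-fold lower. Of the list, 3 members fell without control mouse 1, 2 without control mouse 2, 4 without mutant mouse 1 and 6 without mutant mouse 2. The call of Tk1 was lost without control mouse 2 or 3 (adjusted p up to 0.0666) and that of Cdk1 without control mouse 1 or 2 (up to 0.0591) and with the deposited processed values (0.0703). Of 13 lymphocyte markers, 5 fell and none rose (5 fell adjusted over the list alone), among them Thy1 (log2 -1.21 ± 0.17), which stromal and endothelial cells express too, Nkg7 (-0.99 ± 0.19) and Cd2 (-0.72 ± 0.12). That list shifted down (adjusted p = 0.027; adjusted p = 0.444 with an estimated correlation), but not without mutant mouse 2 (adjusted p = 0.0801), and 3 members fell without control mouse 1 or 2 or mutant mouse 2 or 3.

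The clock and immediate early gene lists shifted up in camera's test with the preset correlation, though most of their members did not pass. Of 15 circadian clock genes 4 rose and none fell (5 rose and 1 fell adjusted over the list alone), and the list shifted up (adjusted p = 0.0332; adjusted p = 0.444 with an estimated correlation). The clock activator gene Arntl was 3.51-fold higher (log2 1.81 ± 0.27; 1.68-fold without background correction), and the repressor genes Cry2 (log2 1.36 ± 0.22), Per1 (1.04 ± 0.15) and Per2 (0.82 ± 0.12) rose with it. The shift was lost without control mouse 3, without mutant mouse 2 (adjusted p up to 0.0840) and among probes detected on all arrays. The time of day at which lungs were taken is not given in the sources used here. Of 21 immediate early and stress genes, 6 rose and none fell (8 rose adjusted over the list alone), led by Fos (log2 1.52 ± 0.33), Fosb (1.15 ± 0.33) and Zfp36 (1.08 ± 0.15), while Egr1 differed by 0.15 ± 0.20 and did not pass. This list shifted up (adjusted p = 0.0332; adjusted p = 0.866 with an estimated correlation; fry adjusted p = 0.151), but not without control mouse 2 or mutant mouse 3 (adjusted p up to 0.0643), among probes detected on all arrays or with array weights. It had 2 risers without control mouse 1 and 3 without control mouse 2, control mouse 3 or mutant mouse 2. Without mutant mouse 3, 1 clock gene and 1 immediate early gene fell. The call of Fos was lost without control mouse 1 (adjusted p = 0.0613) and that of Fosb without any control or mutant mouse 2 or 3 (up to 0.122), without background correction (0.0553, with a 1.33-fold rise), with median scaling (0.0540), without the filter (0.0662) and with array weights (0.0522).

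Targets of p53 moved both ways. Of 19 measured, 6 rose and 2 fell (7 and 2 adjusted over the list alone), and the list did not pass in camera's test (adjusted p = 0.0962). It passed without control mouse 2 (adjusted p = 0.0444) and in fry (0.00712), which does not compare the list with other genes. Besides Cdkn1a, the genes Trp53inp1 (log2 1.96 ± 0.14), Pmaip1 (1.65 ± 0.17, or 0.86 without background correction) and Fas (1.32 ± 0.15), all of the cell death or stress response, were higher, while Phlda3 (-1.27 ± 0.24) and Ccng1 (-0.34 ± 0.10) were lower, the call of Ccng1 being lost without any 1 of the 6 mice (adjusted p up to 0.133), with median scaling (0.0919) and without the filter (0.0697). Of 14 junction genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), with no shift (adjusted p = 0.947): the claudin gene Cldn4 was 4.88-fold higher (2.29-fold without background correction) and the alveolar claudin gene Cldn18 1.73-fold lower, the latter call being lost without control mouse 1 or 2 (adjusted p up to 0.0528). The number of junction genes that fell was 0 without control mouse 1 and 1 without control mouse 2 or 3. Of 16 hypoxia and angiogenic genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; list adjusted p = 0.947; fry adjusted p = 0.0483), Ddit4 and the glucose transporter gene Slc2a1 (2.26-fold) leading the risers, and 2 fell without mutant mouse 3 and 0 without any 1 of the other mice.

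Markers of the airway and alveolar epithelium and of myeloid cells showed no list shift. Of 11 alveolar type 1 markers 1 rose and 3 fell (list adjusted p = 0.713), of 17 alveolar type 2 markers 1 rose and 3 fell (0.601), of 10 ciliated cell markers 1 rose and 1 fell (0.930), and of 10 macrophage markers 1 rose and 1 fell (0.947). In limma's test 0 of 10 club and secretory markers and 0 of 11 neutrophil markers passed (0.947 for each list), and 1 and 0 of them had an unadjusted p below 0.05. That 1 was Gsta3 (log2 0.44 ± 0.15, adjusted p = 0.0707). The alveolar type 2 markers Hc and Cd74 were 3.27-fold and 2.07-fold lower. None of the alveolar type 1 markers passed without control mouse 1 or 2, and 1 fell without mutant mouse 1 or 2. The riser among alveolar type 1 markers was lost without mutant mouse 1 or 3 too (0 rose), and that among alveolar type 2 markers without control mouse 1 or 2 or mutant mouse 1 or 2 (0 rose). Among ciliated markers 0 passed without control mouse 1 or 3 or mutant mouse 1 or 2, and 0 rose and 2 fell without control mouse 2. Among macrophage markers 0 rose without control mouse 1 or 2 or mutant mouse 1 or 2, 2 fell without control mouse 2 or mutant mouse 2, and 2 rose without mutant mouse 3. Without mutant mouse 2, 1 club marker fell, and without control mouse 3 or mutant mouse 3, 1 neutrophil marker fell. Adjusted over each list alone, 1 rose and 3 fell among both alveolar lists, none passed among the club, ciliated and neutrophil lists, and 1 rose and 2 fell among macrophage markers.

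The other lists likewise did not pass in camera's test with all 6 mice. Of 16 interferon response genes 5 fell (5 adjusted over the list alone; list adjusted p = 0.0631), led by Bst2 (2.74-fold) and Gbp2 (2.68-fold), and the count was 8 without mutant mouse 3 and 3 without any 1 of the other mice. The interferon list passed, shifted down, without control mouse 1 (adjusted p = 0.0415), control mouse 3 (0.0338) or mutant mouse 3 (0.00130), with array weights (0.0167) and with the mean of all probes of a gene (0.0436). Of 14 inflammatory genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; 0.866), Vcam1 being 2.69-fold lower and Nfkbia, an NF-κB inhibitor, 2.15-fold higher. Of 6 lymphatic markers 1 rose and 3 fell (1 and 3 adjusted over the list alone; 0.601; fry adjusted p = 0.0233), of 11 venous markers 1 fell (1; 0.590), of 10 platelet genes 2 rose and 2 fell (2 and 2; 0.947), of 15 haem and iron genes 2 rose and 3 fell (2 and 4; 0.827), and of 15 vasoactive genes 1 rose and 1 fell (1 and 0; 0.947). Of 5 erythroid genes 1 fell (2; 0.0963), and Hba-a1, a member of a near-identical globin gene pair, varied among controls by 3.83 (SD, log2) and did not pass. Without control mouse 3, 4 erythroid genes fell and the list passed (adjusted p = 0.0123). Of 9 neighbours of ROSA26 1 fell (0 adjusted over the list alone; 0.80), of 17 mitochondrial respiration genes 2 fell (2; 0.103; without control mouse 3, 3 fell and the list passed at 0.0281, as it did with the deposited processed values at 0.0392), and of 15 ribosomal protein genes 0 passed and 2 had an unadjusted p below 0.05 (0; 0.716). Squamous epithelial genes (4 measured, none past), nerve genes (3 measured, 1 higher) and sex-linked genes (1 measured, not past) were too few to test as lists. Small counts also moved with single mice. Platelet risers were 0 without control mouse 2 or 3 or mutant mouse 2 and 1 without any 1 of the other mice, and those that fell were 0 without control mouse 1 or 2, 4 without control mouse 3 and 1 without mutant mouse 1 or 3. Haem genes that fell were 0 without control mouse 1 and 1 without control mouse 2, and 1 rose without control mouse 1 or 3 or mutant mouse 1 or 2. Without mutant mouse 3, 4 inflammatory genes fell and 2 vasoactive genes rose; 0 vasoactive genes rose without control mouse 1, and 0 fell without any 1 mouse. Venous markers that fell were 2 without control mouse 2 or mutant mouse 3. Erythroid genes that fell were 0 without control mouse 1 or any 1 mutant, and mitochondrial genes 0 without control mouse 1 or 2 or mutant mouse 1 and 1 without mutant mouse 2 or 3. Of the ROSA26 neighbours 1 rose and 1 fell without mutant mouse 2, and 0 passed without any 1 of the other mice. Without control mouse 3, 2 squamous genes rose.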

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

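Of the alternatives given here, the difference of medians for Tmem100 was chosen after the data were seen. Every alternative kept the counts of changed probes within 1.5 times of 3573 except leaving out single mice, where the count was 1679 to 3077, with 780 to 1533 higher and 899 to 1544 lower, from fewer samples. The Tmem100 log2 difference was -4.14 to -1.80 with 1 mouse left out and -1.73 as a difference of medians, and passed only without control mouse 2. With an estimated correlation, 0 lists passed in place of 10. That setting allows for members that vary together, but it also takes its degrees of freedom from the few arrays rather than from the genes. Which of these ended the calls was not tested, so the loss does not show that members varied together. The mouse numbers did not pair the mice: deviations of mice with the same number correlated at -0.0857, -0.0140 and -0.0364, and 0 of the 3 numbers matched best with itself. The replicate block gave 2642 calls, 2516 of them among the 3573, and the skeletal muscle list passed with it (adjusted p = 0.0494). It ended the calls of Ckm (adjusted p = 0.0612), Myl4 (0.0655), Fosb (0.0576), Ccng1 (0.106), Tgm2 (0.0645) and Tsc22d3 (0.0691). Slide as a block was not run, since no slide is named. Among other results, 1630 values of named genes kept direction and side of the threshold, 217 lost the threshold and 13 gained it, and 551, 20 and 24 did so for lists. The count of probes that passed was 3918 without background correction and 2894 with no filter, the latter adjusted over all 25697 probes. Signals near background limit the folds of low probes. Without background correction, the folds of 14 of the 24 largest rises and falls were over 1.5 times smaller.

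Some list means near 0 changed sign, none past the threshold in any setting (lowest adjusted p 0.0926), and the cause was not tested. With 1 mouse left out, the means ranged from -0.0645 to 0.0618 for BMP9-ALK1 signalling, -0.141 to 0.0269 for Notch, -0.101 to 0.125 for club, -0.0704 to 0.168 for ciliated, -0.0560 to 0.0251 for macrophage, -0.384 to 0.588 for neutrophil, -0.338 to 0.0646 for platelet, -0.0823 to 0.0509 for haem, -0.0924 to 0.313 for inflammatory and -0.0207 to 0.148 for vasoactive genes, and the squamous gene Sbsn from -0.437 to 0.0872. The BMP9-ALK1 mean was 0.0107 with probes detected on all arrays and 0.0337 with all probes of a gene. The club mean was 0.0559 with median scaling, 0.0298 with array weights and 0.0452 with all probes, and the ciliated mean -0.0848 with the deposited values. The macrophage mean was 0.0329 with an offset of 50, 0.0600 without background correction, 0.110 with the deposited values, 0.0479 with probes detected on all arrays and 0.00152 with all probes. The neutrophil mean was -0.0387 with median scaling and -0.709 with array weights, and Sbsn was 0.0731 with array weights.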

Other observations

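Tests written only after the result was seen are those of the cardiac muscle and arterial marker patterns; the glucocorticoid list was written after the most changed genes had been seen, and before the values of its own members were. Genes known to be induced by glucocorticoids were on balance higher in mutant lungs in camera's test with a preset correlation (p = 4.61e-05), but not past the threshold with an estimated one (p = 0.0697). Of 19 such genes chosen without Fkbp5, Ddit4 or Cdkn1a, 15 were measured, 9 rose, 1 fell and 5 did not pass, and the mean log2 difference was 0.82 (95% limits 0.52 to 1.13). The fasting and lipid genes Pdk4 (log2 1.90 ± 0.40), Angptl4 (1.78 ± 0.37) and the transporter gene Slc10a6 (1.77 ± 0.25) rose most, followed by the metal-binding gene Mt1 (1.28 ± 0.21) and the kinase gene Sgk1 (1.02 ± 0.15). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose by 0.42 ± 0.10, and Tgm2 was the gene that fell (-0.44 ± 0.11). Both of these calls were lost without any 1 control mouse or mutant mouse 1 or 2 (adjusted p up to 0.0863), that of Tgm2 also with median scaling (0.0630), and that of Angptl4 without control mouse 2 (0.0519).

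The broad change between the groups, 3573 probes, has several candidate explanations besides the loss of Tmem100. A difference between the groups in chip or time of day could not be tested, since neither is given in the sources used here. Of the 10 splits of the 6 mice into 3 and 3, 1 gave as many probes, the real split itself, and the highest of the others gave 1 probe. Every other split mixes mutants with controls, so the group difference adds to its spread and few calls can follow. In addition, 10 splits are too few for a share below 0.05. Strain-derived sequence around the ROSA26 knock-in could alter genes near it. Of 2552 changed genes, 51 (2.00%, exact 95% limits 1.49 to 2.62) lie within 20 Mb of the locus. The share among the 9380 tested genes with a position was 1.63% (two-sided Fisher's exact p = 0.0987). All the other changed genes lie outside this window, which argues against local sequence within it as the source of most of the change. The window holds only 153 tested genes, too few for the share to show whether genes inside it were affected. An effect of such sequence on genes elsewhere was not tested and remains open. DNA damage by CreER, which only the mutants carry, remains open: the mean of the p53 target list was 0.436 higher (95% limits 0.356 to 0.515), but its rise against other genes did not pass in camera's test (adjusted p = 0.0962; 0.0444 without control mouse 2) while fry, which sets no other genes against it, did pass (0.00712), and controls with CreER and no floxed allele, which would part the enzyme from the deletion, were not analysed here. A glucocorticoid response in the mutants may account for part of the change, since the added list shifted up (mean 0.822, camera p = 4.61e-05, or 0.0697 with an estimated correlation). Only lung RNA was measured, so whether such a response was systemic, or came from illness, stress or the time of day, is not known. Whether the shift of the list follows from the loss of Tmem100 was not tested.

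Lower cardiac muscle signals in mutant lungs may reflect how much heart, great vessel or skeletal muscle tissue came with each lung, which the table does not decide. The range of the cardiomyocyte list mean among control mice was 1.18, 0.760 of the difference between the groups (1.56), but this rests on control mouse 2: without it the range was 0.324 and the ratio 0.266, and without control mouse 1 the ratio was 0.475. All 3 mutants lay below all 3 controls. Myl4 and Nppa, whose probes had the highest signals of the list, were at 14.25 and 13.14 in controls and at 13.01 and 12.40 in mutants, though signals of different probes do not rank abundance. None of the 15 measured members is in another list, but cardiac muscle also surrounds the pulmonary veins of mice, so a change within the lung remains open, as does the genotype.

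Fewer endothelial cells in the mutant lungs could lower all endothelial markers alike, whereas the arterial markers fell further than the other pan-endothelial markers. This comparison was written after the arterial fall had been seen. Its outcome was not independent of that choice, so it does not decide the cause. The 14 arterial markers were lower by a mean of -0.90 and the 21 other pan-endothelial markers by -0.37, a gap of -0.533 between the groups (95% limits -0.683 to -0.383). General capillary markers had a similar median (-0.90) and a mean of -0.71, but 6 of these 9 markers are also in other lists, and whether the gap is particular to arteries was not tested. A loss confined to arterial cells, or lower transcription of arterial genes after the loss of Tmem100, remains open and was not tested. Less great vessel tissue in the mutant samples also remains open, since 11 of 17 smooth muscle markers and 10 of 18 matrix genes were lower as well.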
